A study of Mus musculus with 46 samples.

How the data were processed

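Polyadenylated RNA of whole livers was sequenced from male C57BL6 mice, 30 days after an adeno-associated virus had been given per the series' design text. The labels' protocols name a Trizol and chloroform extraction and a poly(A) selection kit. The reads were aligned with STAR and counted with HOMER on mm10 (GRCm38), per the submitters' processing notes, which give no versions. Raw reads over the exons of each gene were counted on the plus strand setting with the transcripts of a gene condensed into 1 entry, per the file headers. The deposited values are 2 tables of raw counts per gene with 24537 genes each, named by RefSeq transcript, of which 23603 carry the same transcript in both tables and 934 a different one. In the batch 1 table the deposited counts are whole numbers. In the table of batch 2, 50.6% to 52.8% of the values in a library are not whole and lie on steps of 0.5, so these deposited values were handled like estimated counts, without normalization, and rounded to whole numbers (ties to even) before testing. The step that gave values of this kind is not given in the sources used here.

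Libraries were grouped by the transgene and the age in the labels. Mice of one age in one batch share a birth date and a cull date in the labels. The labels give each library its own name and do not say that each comes from a separate mouse, so p-values measure the spread between these libraries, which may in part be technical. Age in days was computed from the 2 dates. For 2 libraries the title and the age disagree, and they were left in no group. No column of per-sample values was left without a sample. The depth was 14791332 to 24504583 counts in genes per library in batch 1, which is 79.8% to 85.7% of the total given in the column names, and 7907087 to 11233482.5, or 42.5% to 44.3%, in batch 2. Genes overlapped on the other strand by a gene at least 16 times as abundant were higher in batch 2 than in batch 1 by a median log2 value of 2.06 (quartiles 0.69 and 4.02, 445 genes), against 0.04 for 13183 genes with no gene on the other strand. Genes with such a neighbour (here Cdc20, Kif20a, Cxcl10, Nop56 and H2-T23) are therefore uncertain in batch 2, and so are genes with near-identical copies, whose reads the counting could split. All 78 pairs of libraries within a group and batch differed by more than sampling noise (chi-square per degree of freedom 6.46 to 297.12), as did the 2 libraries in no group (37.39), so none was counted as a repeat.

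Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr with its defaults (minimum count 10, minimum total 15), a quasi-likelihood fit with robust settings and F-tests, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Comparisons without Myc used the 44 grouped libraries with batch as a covariate. Comparisons with Myc used the 27 libraries of batch 1, where all Myc libraries are. The 2 differences of effects were tested as interaction contrasts. The design had assumed whole counts in both tables. Fold changes are on the log2 scale with edgeR's prior count of 0.125, and standard errors come from the F statistic. A gene "rose" or "fell" where it passed this test. CPM values per library use the effective library sizes over all 46 libraries, and means of a list are over log2 CPM with a pseudocount of 0.5 counts.

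The 35 gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. They cover interferon-stimulated genes, interferon-gamma-inducible GTPases and chemokines, MHC class I and class II genes, DNA replication, mitosis, p53 targets, senescence-associated secretory genes, ribosome biogenesis, nucleotide synthesis, cytosolic ribosomal proteins, stress responses, hepatocyte identity, pericentral and periportal genes, xenobiotic metabolism, male-biased and female-biased genes, cholesterol synthesis, lipogenesis, fatty acid oxidation, bile acids, the acute phase, the clock, immediate early genes, fetal genes, red blood cells, and markers of Kupffer cells, monocytes, T and NK cells, B cells, neutrophils, stellate cells, endothelium and bile ducts. Each was tested against the other genes with camera (limma 3.58.1, preset correlation between genes 0.01), adjusted over the lists of a comparison. The rule for named genes takes Ccnd1 and Myc everywhere, up to 6 genes with the highest and 6 with the lowest fold change among those past the threshold at a mean of at least 1 CPM (no predicted or immunoglobulin genes, and the same sign in both batches where both hold the groups), up to 3 members of each list past the threshold by adjusted p, and 4 interferon-stimulated genes in every comparison. Not every gene it allows is printed, and some genes are not reported here. In the age comparisons of the Ccnd1 and of the Myc livers the design had planned to name only Ccnd1, Myc and interferon-stimulated genes, and members of other lists that passed are printed too, as the rule allows.

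Alternatives fixed in advance were DESeq2 1.42.0, DESeq2-type size factors or total counts for scaling, no filter or a stricter one (1 CPM in 5 libraries), no batch term, a mean for each group in each batch, each batch alone, only the groups compared, at least a 2-fold change, an estimated correlation in camera, Spearman's rho, called genes only, and leaving out each library in turn for the counts of genes and the interferon-stimulated list. Added after seeing the data were doubling the batch 2 values, leaving out libraries with a TMM factor above 1.3, leaving out libraries with over 1 CPM of the pancreatic gene Cpa1, leaving out each library in turn for the other gene lists, and leaving out young Myc replicate 1 for 4 leukocyte genes. The edgeR code was tested on simulated data. Of genes changed 1.5-, 2- and 4-fold, it recovered 62.7%, 83.6% and 98.5% in the Ccnd1 comparison in young livers (14053 genes, 0.6% of calls false) and 22.4%, 73.1% and 97% in the Myc comparison in young livers (13651 genes, 3.8% false). Floors of 3 counts, up to 0.439 CPM in a library, cover counting error only. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.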

Results

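Liver RNA was sequenced from young and old male C57BL6 mice 30 days after they had received an adeno-associated virus, a vector that brings a gene into hepatocytes. The vector over-expressed Ccnd1 (cyclin D1, which takes cells from G1 into S phase), Myc (a transcription factor that drives cell growth) or, in the controls, mApple, a red fluorescent protein. The design asks what each oncogene changes in the liver, what age changes, and whether the oncogene's effect depends on the age of the liver. Of 46 libraries, 44 fall into 6 groups: 10 young mApple, 9 old mApple, 8 young Ccnd1, 8 old Ccnd1, 4 young Myc and 5 old Myc livers. The other 2 carry a title and an age that disagree, and they enter no comparison. The libraries form 2 batches with separate count tables. Batch 1 holds 27 libraries, among them every Myc library, of mice aged 141 or 626 days. Batch 2 holds 19 libraries of mice aged 114 or 737 days. A total of 14874 to 16288 genes had a count in a batch 1 library and 15524 to 16966 in a batch 2 library.

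Each transgene was abundant in the livers that had received it. Ccnd1 (transcript NM_007631, chromosome 7, 144929931 to 144939925, minus strand, mm10) lay at 34.4 ± 10.9 CPM (counts scaled to a common library size; SD, n = 10) in young mApple livers and at 707.5 ± 97.6 (n = 8) in young Ccnd1 livers. In old livers it lay at 46.1 ± 31.8 (n = 9) with mApple and at 445 ± 144.6 (n = 8) with Ccnd1. The log2 fold change was 4.41 ± 0.33 (SE, adjusted p = 4.56e-12) in young and 3.24 ± 0.33 (adjusted p = 4.19e-08) in old livers. Adjusted over all genes tested, the difference between them, -1.17 ± 0.44, did not pass (adjusted p = 0.415), although its size exceeds 2 SE. Myc (transcript NM_001177354, chromosome 15, 61985341 to 61990361, plus strand) rose in batch 1 from 7.6 ± 3.77 CPM (n = 5) to 39.6 ± 10.9 (n = 4) in young livers and from 7.3 ± 4.76 (n = 5) to 37.1 ± 5.56 (n = 5) in old livers. Its log2 fold change was 2.38 ± 0.4 in young and 2.35 ± 0.38 in old livers (adjusted p = 0.000362 and 0.000117). Old and young Myc livers differed in Myc by -0.08 ± 0.38 (adjusted p = 0.952). The counts cover all exons of a gene, so transcripts of the vector and of the mouse's own gene are counted together where they share sequence.

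**Figure D1:**
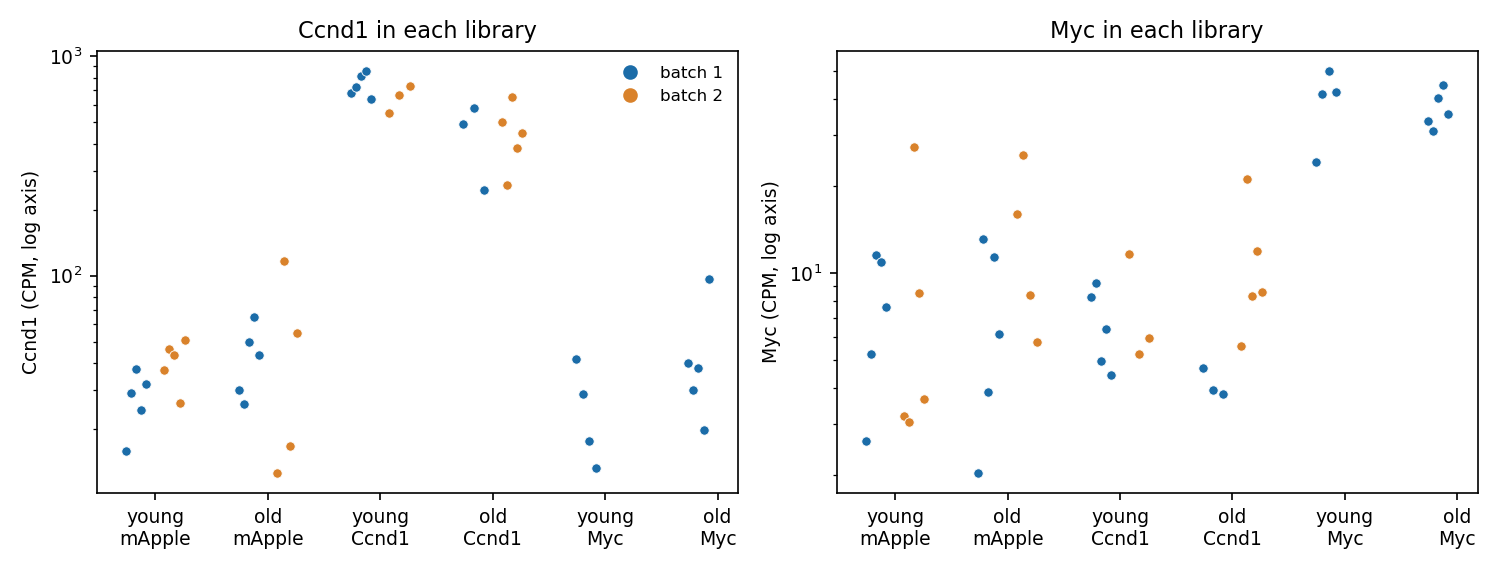
Ccnd1 (left) and Myc (right) in CPM on a log axis, 1 point per library, blue for batch 1 and orange for batch 2. The Ccnd1 livers (means 707.5 young and 445 old) lie above all other groups in Ccnd1, and the Myc livers (means 39.6 young and 37.1 old) hold the highest group means of Myc.

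Ccnd1 against mApple in young livers showed what cyclin D1 changes in the young tissue. Most genes of mitosis and of the interferon response rose, as did 14 of 34 DNA replication genes, whose list lost its call (adjusted p = 0.0555 with an estimated correlation). Of 28 mitosis genes, 24 rose (27 adjusted over the list alone), with a median log2 fold change of 1.69, among them Ccnb1 (cyclin B1, the Cdk1 partner of mitosis) by 2.95 ± 0.5 and Plk1 (a mitotic kinase, chromosome 7, 122159435 to 122169884) by 2.73 ± 0.48. Of 42 interferon-stimulated genes, 24 rose (37 adjusted over the list alone), with a median of 0.86. They included Irf7 (a transcription factor of the interferon response, chromosome 7, 141263183 to 141266424) at 1.58 ± 0.21 (adjusted p = 1.14e-05), Usp18 (a brake on interferon signalling) at 1.37 ± 0.23 and Oas1a (an antiviral RNA sensor with close paralogs, hence uncertain) at 2.1 ± 0.3. Both lists stood above the other genes (camera adjusted p = 1.03e-45 and 3.49e-46), also with an estimated correlation (adjusted p = 0.0228 for each).

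Of 34 DNA replication genes, 14 rose in the young Ccnd1 livers (24 adjusted over the list alone; median 0.72), led by Mcm6 (a subunit of the replicative helicase, chromosome 1, 128331575 to 128359705) at 1.92 ± 0.26, Mcm4 at 1.33 ± 0.23 and the licensing factor Cdt1 at 1.45 ± 0.25. The list's adjusted p was 1.04e-23, and adjusted p = 0.0555 with an estimated correlation. Of 18 genes of MHC class I antigen presentation, 8 rose (14 adjusted over the list alone; median 0.43), among them Tapbp by 0.61 ± 0.14 and Nlrc5, a transcription factor of these genes, by 0.62 ± 0.16. MHC class I presentation as a list had adjusted p = 2.28e-11, and adjusted p = 0.0905 with an estimated correlation. Of 20 interferon-gamma-inducible GTPases and chemokines, 3 rose (7 adjusted over the list alone; median 0.62). Interferon-gamma-inducible genes as a list had adjusted p = 3.25e-08, and adjusted p = 0.398 with an estimated correlation. Of 22 p53 targets, the death receptor gene Tnfrsf10b (1.46 ± 0.31) and Eda2r (1.2 ± 0.3) rose (2 also adjusted over the list alone; median 0.23). The p53 targets as a list had adjusted p = 0.00193, and adjusted p = 0.398 with an estimated correlation, and their median was 0.09 without young Ccnd1 replicate 8. Gsta1, a glutathione transferase whose reads can be shared with Gsta2, rose by 2.77 ± 0.49. Genes that fell included Elovl6 (fatty acid elongation, -1.16 ± 0.34), Mid1ip1 (a partner of acetyl-CoA carboxylase, -0.97 ± 0.23) and Igfbp2 (-0.96 ± 0.26), and albumin (Alb) fell by 0.53 ± 0.15 on the log2 scale. Myc stood at -0.16 ± 0.38 (adjusted p = 0.88).

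In all, 418 of 14232 genes tested passed in young Ccnd1 livers, 331 higher and 87 lower, and 13 of 35 gene lists did, 2 of them also with an estimated correlation. With no batch term 192 genes passed, and without the libraries with TMM factors above 1.3, a setting chosen after the data were seen, 638 did. Batch 1 alone called 265 genes and batch 2 alone 11. In the same order the medians were 0.78 and 0.9 for the interferon-stimulated genes, 1.42 and 2.36 for mitosis, and 0.29 and 1.24 for DNA replication. With libraries scaled to their total counts, 438 genes were higher and 19 lower.

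Ccnd1 against mApple in old livers gave the same question in aged tissue. Of the 42 interferon-stimulated genes, 22 rose (36 adjusted over the list alone) with a median log2 fold change of 0.97. They included Usp18 (chromosome 6, 121245906 to 121270917) at 1.68 ± 0.24 (adjusted p = 8.49e-05), Bst2 (tetherin, which holds back virus particles) at 1.02 ± 0.15, Irf7 at 1.33 ± 0.21 and Ifi44 at 2.06 ± 0.38. Of 34 DNA replication genes, 9 rose (26 adjusted over the list alone; median 0.66), among them Mcm6 by 1.43 ± 0.27 and Chaf1a (histone deposition behind the replication fork) by 1.36 ± 0.28. Of 28 mitosis genes, 4 rose (27 adjusted over the list alone, median 1.18), among them Aurka (a spindle kinase counted on different transcripts in the 2 tables, 1.35 ± 0.25) and Ect2 (cytokinesis, 1.48 ± 0.31). The mitosis median ranged from 1.03 to 1.83 with 1 library left out. Of 18 MHC class I presentation genes, 3 rose (9 adjusted over the list alone; median 0.42), among them H2-K1 by 0.5 ± 0.1 and H2-Q7 by 0.68 ± 0.14, which share sequence with other class I genes and are uncertain. These 4 lists passed with camera (adjusted p = 4.18e-71, 3.47e-34, 7.21e-39 and 5.14e-14) and with an estimated correlation (adjusted p = 0.00186, 0.0127, 0.0272 and 0.0406).

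Of 23 genes of xenobiotic metabolism, 4 rose in the old Ccnd1 livers (5 adjusted over the list alone, median 0.16, or 0.11 to 0.35 with 1 library left out). These were the quinone reductase Nqo1 (0.89 ± 0.19), the carbonyl reductase Cbr3 (1.82 ± 0.41), Gsta1 (3.02 ± 0.55) and its near-identical copy Gsta2, named here after its values were seen. Xenobiotic metabolism as a list had adjusted p = 7.66e-06, and adjusted p = 0.275 with an estimated correlation. Gstm3, another glutathione transferase with close paralogs, rose by 1.9 ± 0.48. The steroid hydroxylase Cyp2a4, nearly identical to Cyp2a5 and so uncertain, rose by 4.03 ± 0.7. Cyp21a1 (-2.53 ± 0.51), the trehalase gene Treh (-2.06 ± 0.49), the anion transporter gene Slc22a7 (-1.83 ± 0.44) and Socs2, a target and brake of growth hormone signalling (-1.59 ± 0.41), fell. The T and NK cell (median 0.81), B cell (0.57) and MHC class II (0.56) lists passed as higher with 0 members past edgeR over all genes (adjusted p = 3.01e-07, 1.16e-06 and 0.000118, and adjusted p = 0.339, 0.291 and 0.419 with an estimated correlation). Without old Ccnd1 replicate 5 the T and NK and MHC class II medians were 0.41 and 0.23, still past the threshold. With 1 library left out the T and NK, B cell and MHC class II medians reached 1.51, 1.2 and 1.04 at most. The 24 acute phase genes had a median of -1.47, with 19 lower when adjusted over the list alone and 0 by edgeR over all genes tested (list adjusted p = 2.61e-11, and adjusted p = 0.339 with an estimated correlation). Their median was 0.02 in batch 1 and -2.42 in batch 2, where Saa1, chosen after its values were seen, reached 9471.3, 5065.3 and 1075.2 CPM in old mApple replicates 6, 8 and 9.

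In all, 125 of 14232 genes passed in old Ccnd1 livers, 104 higher and 21 lower, and 19 of 35 lists did, 4 of them also with an estimated correlation. Libraries scaled to their total counts moved the median of all genes by 0.14 on the log2 scale. The count rose to 1237 without old mApple replicate 7 and fell to 65, 75 and 76 without old Ccnd1 replicates 1, 2 and 5 and to 80 and 77 without old mApple replicates 6 and 8. Of 100 splits of these libraries, the real one included, 6 called at least 125 genes. The count was 12 when only the groups compared were fitted, 62 with no batch term, 229 in DESeq2 and 497 without the libraries with TMM factors above 1.3. Batch 1 alone called 162 higher and 17 lower genes and batch 2 alone 91 higher and 151 lower, so the balance turned between the batches, whose fold changes correlated across genes with r = 0.044. The interferon-stimulated medians were 1.17 and 0.56 and the mitosis medians 1.84 and 0.5, batch 1 first.

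**Figure D2:**
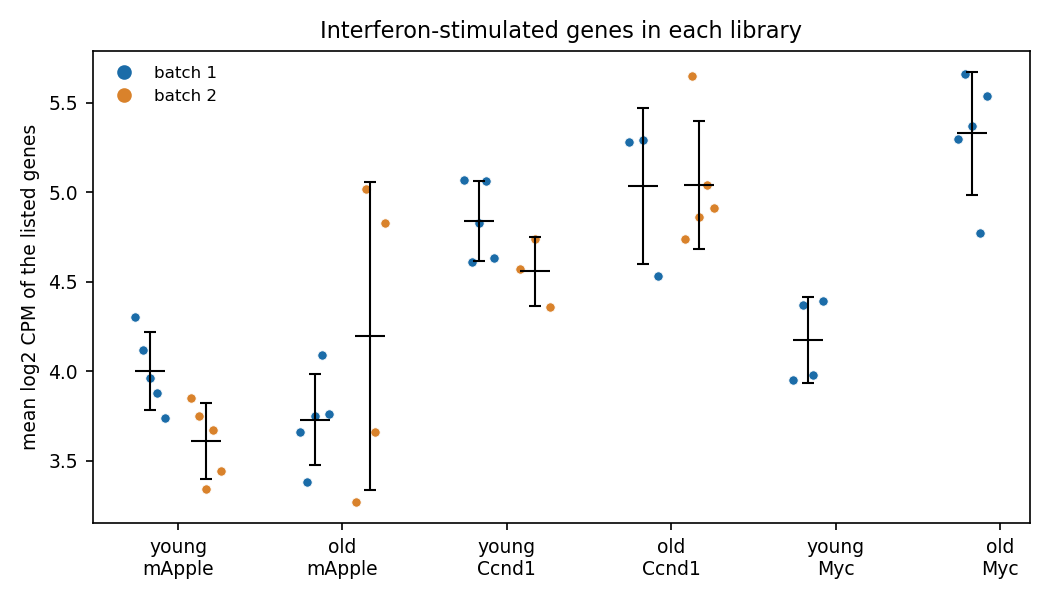
Mean log2 CPM of the interferon-stimulated genes, 1 point per library, with the mean and SD of each group in each batch. In batch 1 the old Myc livers (5.33 ± 0.34) lie above the young Myc livers (4.17 ± 0.24), while the young and old Ccnd1 livers (4.84 ± 0.22 and 5.04 ± 0.44) both lie above their mApple controls.

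The difference of the Ccnd1 effect between old and young livers tested whether age alters the response to cyclin D1. Ccnd1 RNA itself rose less in old than in young livers, by more than 2 SE, so age and transgene level cannot be told apart here. The interferon-stimulated genes differed by a median log2 value of -0.02, and the list did not pass (camera adjusted p = 0.351). Bst2 (0.57 ± 0.21) and Ifit3 (0.88 ± 0.4) had the smallest p-values in that list and did not pass (adjusted p = 0.407 and 0.519). The acute phase genes differed by a median of -2.11, with 21 of 24 lower when adjusted over the list alone and 0 over all genes (list adjusted p = 1.98e-17, and adjusted p = 0.524 with an estimated correlation). Hp (haptoglobin, -2.52 ± 0.7) and Orm1 (-2.71 ± 0.79) had adjusted p = 0.311 and 0.315. The 23 lipogenesis genes had a median difference of 0.51, with 3 higher when adjusted over the list alone, among them Elovl6 (1.71 ± 0.49) and Acaca (0.76 ± 0.24). The lipogenesis list had adjusted p = 5.54e-07, and adjusted p = 0.524 with an estimated correlation.

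No gene passed for this difference in edgeR (0 of 14232; 1280 at an unadjusted p under 0.05), and DESeq2 called 22. Batch 1 alone called 0 and batch 2 alone 28, 3 higher and 25 lower. Without young mApple replicate 2 the count was 4, and without old mApple replicates 1 or 6 or old Ccnd1 replicates 5 or 7 it was 1. The median difference of the interferon-stimulated genes was 0.36 in batch 1, where the list passed, and -0.31 in batch 2. Over both batches the list passed without old mApple replicate 7 (0.17) and without old mApple replicate 9 (0.12).

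Myc against mApple in young livers showed what Myc changes in the young tissue. Ribosome biogenesis (31 of 39 genes), nucleotide synthesis (12 of 21) and mitosis (27 of 28) rose, while 9 of 19 cholesterol synthesis and 6 of 23 lipogenesis genes fell. The mitosis, cholesterol synthesis and lipogenesis lists lost their calls (adjusted p = 0.0725, 0.305 and 0.358 with an estimated correlation). Of 39 ribosome biogenesis genes, 31 rose (34 adjusted over the list alone; median log2 fold change 0.7), led by Nop2 (a methyltransferase of ribosomal RNA, chromosome 6, 125131883 to 125144753) by 1.07 ± 0.11 (adjusted p = 1.1e-06) and Nop56 by 1.19 ± 0.13. Of 21 nucleotide and one-carbon synthesis genes, 12 rose (14 adjusted over the list alone; median 0.54), among them Ctps (CTP synthase, chromosome 4, 120539868 to 120570276) by 1.44 ± 0.19 and Atic (purine synthesis) by 0.74 ± 0.1. Both lists passed (camera adjusted p = 2.96e-30 and 7.47e-09), also with an estimated correlation (adjusted p = 0.00037 and 0.000282).

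Of 28 mitosis genes, 27 rose in young Myc livers (27 adjusted over the list alone; median 2.3), among them Cdc20 by 3.17 ± 0.44, Kif20a by 2.84 ± 0.4 and Cdca8 by 2.24 ± 0.32. Mitosis as a list had adjusted p = 2.57e-33, and adjusted p = 0.0725 with an estimated correlation. Of 34 DNA replication genes, 10 rose (13 higher and 1 lower adjusted over the list alone; median 0.51), among them Ccne1 (cyclin E1) by 2.2 ± 0.33 and Mcm6 by 1.5 ± 0.21. DNA replication as a list had adjusted p = 1.67e-06, and adjusted p = 0.279 with an estimated correlation. Of 27 cytosolic ribosomal protein genes, 15 rose (17 adjusted over the list alone; median 0.56). Ribosomal proteins as a list had adjusted p = 2.72e-11, and adjusted p = 0.288 with an estimated correlation. Of 22 p53 targets, 6 rose (7 adjusted over the list alone, median 0.27, or 0.15 to 0.37 with 1 library left out), among them Zmat3 by 1.27 ± 0.17 and Eda2r by 2.63 ± 0.41. The p53 targets as a list had adjusted p = 0.000508, and adjusted p = 0.279 with an estimated correlation. The 42 interferon-stimulated genes had a median of 0.02 and the list did not pass (adjusted p = 0.256), although 4 members rose, among them Oas1a by 1.54 ± 0.32, Oas2 by 1.14 ± 0.25 and Lgals3bp by 0.84 ± 0.15.

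Of 19 cholesterol synthesis genes, 9 fell in young Myc livers (13 adjusted over the list alone; median -0.71), among them Sc5d (a sterol desaturase, -1 ± 0.2). Cholesterol synthesis as a list had adjusted p = 2.9e-07, and adjusted p = 0.305 with an estimated correlation. Of 23 lipogenesis genes, 6 fell (10 lower and 1 higher adjusted over the list alone; median -1.05), among them Elovl5 (-1.69 ± 0.36) and Scd1 (stearoyl-CoA desaturase, -2 ± 0.52). Lipogenesis as a list had adjusted p = 1.17e-05, and adjusted p = 0.358 with an estimated correlation. Of 25 fatty acid oxidation genes, 3 fell (3 adjusted over the list alone; median -0.39), among them Fabp1 (-1.01 ± 0.26). Fatty acid oxidation as a list had adjusted p = 0.00681, and adjusted p = 0.765 with an estimated correlation. Of 23 hepatocyte identity genes, 6 fell (7 adjusted over the list alone, median -0.21, or -0.29 to -0.13 with 1 library left out), among them Alb (-0.7 ± 0.14) and Foxa2 (-0.9 ± 0.18). Hepatocyte identity as a list had adjusted p = 0.00681, and adjusted p = 0.288 with an estimated correlation. Of 18 pericentral genes, 3 fell and 1 rose (likewise adjusted over the list alone; median -0.42). Pericentral genes as a list had adjusted p = 0.0229, and adjusted p = 0.638 with an estimated correlation. Without young Myc replicate 1 neither the fatty acid oxidation nor the pericentral list passed (medians -0.23 and -0.3, adjusted p = 0.36 and 0.255). Of 9 fits with 1 library left out, the fatty acid oxidation call ended in 1 and the pericentral call in 2. Mycn, a relative of Myc (-2.61 ± 0.45), and Srgap3 (chromosome 6, 112717972 to 112947266, -3.49 ± 0.31) also fell. Of 14 monocyte and infiltrating macrophage markers, 6 rose (7 adjusted over the list alone; median 1.36), among them Cx3cr1 (1.37 ± 0.31) and Ly6c2 (2.58 ± 0.63). Monocyte markers as a list had adjusted p = 0.00576, and adjusted p = 0.653 with an estimated correlation. Young Myc replicate 1 stood apart in these markers, with a mean of 3.49 log2 CPM against 1 to 1.39 in the other 3 young Myc libraries and up to 1.54 in young mApple libraries of batch 1. Without it 2 of the 14 markers rose and 1 fell, the median was 0.12 and the list did not pass (adjusted p = 0.537), with Cx3cr1 at 1.19 ± 0.33 (adjusted p = 0.0174) and Ly6c2 at 1.1 ± 0.52 (adjusted p = 0.169). The leukocyte genes Ngp (6.18 ± 1.61) and Chil3 (5.64 ± 1.35), among the highest by the fixed rule, rested on the same library, where Ngp lay at 62.5 CPM against 0 to 1.15 in the other 3. Without it they stood at 0.87 ± 1.39 and 0.92 ± 1.05 (adjusted p = 0.729 and 0.604). The pancreatic genes Pnlip (7.29 ± 2.36) and Ctrl (5.96 ± 1.68) were also among the highest. Young Myc replicates 2 and 4 held 6.62 and 24.85 CPM of the pancreatic gene Cpa1, chosen after its values were seen.

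In all, 1829 of 13793 genes passed in young Myc livers (n = 4 against 5), 1143 higher and 686 lower, and 13 of 35 lists did, 2 of them also with an estimated correlation. Libraries scaled to their total counts moved the median of all genes by 0.13 on the log2 scale and gave 2024 higher and 271 lower genes, and without young Myc replicate 3 the count was 1067. It was 497 when only the groups compared were fitted.

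Myc against mApple in old livers gave a rise of cell division, ribosome assembly and interferon genes. Of 42 interferon-stimulated genes, 39 rose (41 adjusted over the list alone) with a median log2 fold change of 1.41. They included Oasl2 (chromosome 5, 114896934 to 114912245) at 3.19 ± 0.29 (adjusted p = 4.69e-08), Lgals3bp at 1.6 ± 0.15 and Mx1 (a GTPase against influenza viruses, chromosome 16, 97447037 to 97462905) at 2.76 ± 0.27. All 28 mitosis genes rose (28 adjusted over the list alone; median 2.94), among them Aurka by 3.05 ± 0.33 and Cdk1 by 2.84 ± 0.31. Of 34 DNA replication genes, 22 rose (25 adjusted over the list alone; median 0.76), among them Chaf1a by 2.14 ± 0.22 and Mcm6 by 1.98 ± 0.21. Of 39 ribosome biogenesis genes, 34 rose (34 adjusted over the list alone; median 0.75), among them Nop56 by 1.06 ± 0.12 and Nop2 by 0.92 ± 0.11. Of 21 nucleotide and one-carbon synthesis genes, 11 rose (11 higher and 1 lower adjusted over the list alone; median 0.5), among them Ctps by 1.88 ± 0.18. These 5 lists passed with camera (adjusted p = 5.4e-49, 1.69e-49, 5e-16, 8.14e-30 and 1.64e-05) and with an estimated correlation (adjusted p = 0.00657, 0.00807, 0.00972, 0.000798 and 0.00488).

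Of 22 p53 targets, 11 rose in old Myc livers (14 adjusted over the list alone; median 0.58), among them Tnfrsf10b by 2.36 ± 0.33 and Zmat3 by 1.31 ± 0.17. The p53 targets as a list had adjusted p = 7.35e-07, and adjusted p = 0.0388 with an estimated correlation. Of 20 interferon-gamma-inducible genes, 14 rose (14 adjusted over the list alone; median 1.02), among them Gbp3 (one of a family of close paralogs, chromosome 3, 142560052 to 142573212) by 2.49 ± 0.26, the chemokine gene Cxcl10 by 2.22 ± 0.31 and Igtp by 1.3 ± 0.21. Interferon-gamma-inducible genes as a list had adjusted p = 8.36e-12, and adjusted p = 0.0667 with an estimated correlation. Of 18 MHC class I presentation genes, 12 rose (12 adjusted over the list alone; median 0.56), among them the peptide transporter gene Tap1 (chromosome 17, 34187556 to 34197225) by 1.02 ± 0.15. MHC class I presentation as a list had adjusted p = 9.21e-07, and adjusted p = 0.11 with an estimated correlation. Of 23 xenobiotic metabolism genes, 9 rose (9 adjusted over the list alone; median 0.62), led by Cbr3 (chromosome 16, 93683219 to 93690991) by 5.09 ± 0.36 (adjusted p = 5.19e-10), Gsta1 by 4.39 ± 0.52 and Nqo1 (chromosome 8, 107388225 to 107403205) by 1.95 ± 0.22. Xenobiotic metabolism as a list had adjusted p = 9.75e-06, and adjusted p = 0.21 with an estimated correlation.

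Of 23 hepatocyte identity genes, 8 fell in old Myc livers (9 adjusted over the list alone; median -0.33), among them Alb (-0.75 ± 0.13) and Apoa1 (-0.75 ± 0.16). Hepatocyte identity as a list had adjusted p = 0.000247, and adjusted p = 0.0667 with an estimated correlation. Of 17 male-biased liver genes, 6 fell (6 lower and 1 higher adjusted over the list alone; median -0.57), among them the complement gene C6 (-1.23 ± 0.17) and Elovl3 (-2.15 ± 0.38). The male-biased genes as a list had adjusted p = 0.0017, and adjusted p = 0.421 with an estimated correlation, and their median was -0.32 without old mApple replicate 2. Of 19 cholesterol synthesis genes, 9 fell (11 adjusted over the list alone; median -0.58). Cholesterol synthesis as a list had adjusted p = 1.23e-05, and adjusted p = 0.365 with an estimated correlation. Srgap3 (-3.21 ± 0.28) and Mycn (-3.07 ± 0.44) fell as well. Of 20 endothelial markers, 2 fell (1 adjusted over the list alone; median -0.35), among them Tek (-0.91 ± 0.21). The endothelial markers as a list had adjusted p = 0.0101, and adjusted p = 0.552 with an estimated correlation. Of 14 monocyte and infiltrating macrophage markers, 5 rose (6 higher and 1 lower adjusted over the list alone; median 0.79), and of 14 MHC class II and dendritic cell markers 2 rose (1 adjusted over the list alone; median 0.65). These lists had adjusted p = 0.0168 and 0.0157, and adjusted p = 0.552 with an estimated correlation for each, and neither passed without old mApple replicate 2 (adjusted p = 0.0698 and 0.105). The Kupffer, T and NK, B cell and neutrophil markers did not pass as lists (medians 0.31, 0.4, 0.33 and -0.67, adjusted p = 0.641, 0.373, 0.783 and 0.646).

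In all, 2367 of 13793 genes passed in old Myc livers (n = 5 against 5), 1493 higher and 874 lower, and 17 of 35 lists did, 6 of them also with an estimated correlation. Libraries scaled to their total counts moved the median of all genes by 0.21 on the log2 scale and gave 3170 higher and 314 lower genes.

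**Figure D3:**
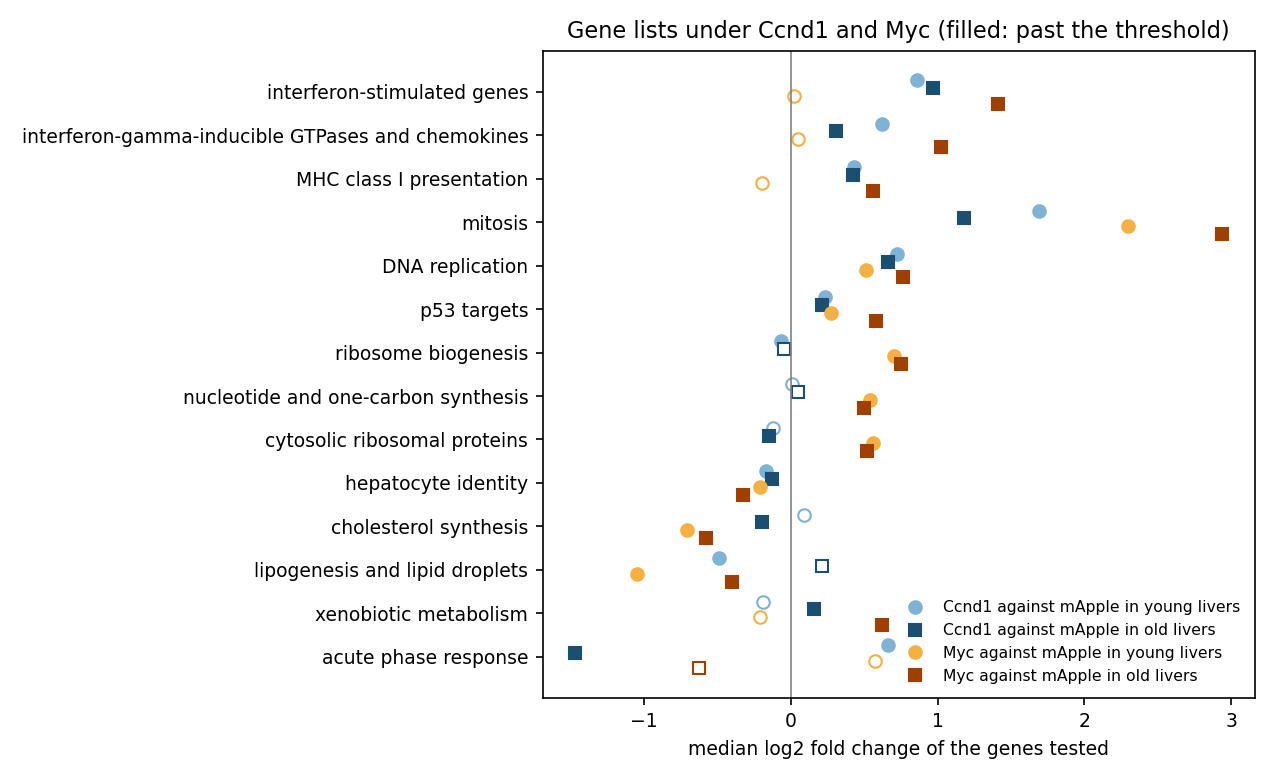
Median log2 fold change of 14 gene lists under Ccnd1 (blue) and Myc (orange and brown) in young (circles) and old (squares) livers, filled where the list passed with camera. The interferon-stimulated genes lie at 0.86 and 0.97 under Ccnd1, at 0.02 under Myc in young livers and at 1.41 under Myc in old livers.

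The difference of the Myc effect between old and young livers tested whether age alters the response to Myc. Of the interferon-stimulated, MHC class I and xenobiotic metabolism genes, 17 of 42, 4 of 18 and 4 of 23 rose more under Myc in old than in young livers. Of 42 interferon-stimulated genes, 17 passed for the difference (35 adjusted over the list alone), all of them higher, with a median log2 difference of 1.4 (camera adjusted p = 1.6e-64, and adjusted p = 0.00405 with an estimated correlation). Mx1 rose by 2.76 ± 0.27 in old livers and stood at 0.28 ± 0.28 in young ones, a difference of 2.48 ± 0.38 (adjusted p = 0.00123). The differences were 2.58 ± 0.4 for Oasl2, 2.91 ± 0.46 for Isg15 (a ubiquitin-like modifier, chromosome 4, 156199424 to 156200818), 2.84 ± 0.45 for Rsad2 (viperin) and 3 ± 0.57 for Ifi44.

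Of 18 MHC class I presentation genes, 4 passed for the difference of the Myc effect (13 adjusted over the list alone; median 0.72; camera adjusted p = 2.26e-17, and adjusted p = 0.0108 with an estimated correlation). Among them were Tap1 (1.04 ± 0.22) and H2-T22 (0.97 ± 0.2) and H2-T23 (1.19 ± 0.23), the last 2 uncertain for their paralogs. Of 20 interferon-gamma-inducible genes, 3 passed (14 adjusted over the list alone; median 1.05; adjusted p = 2.27e-17, and adjusted p = 0.0252 with an estimated correlation), namely Gbp3 (2.41 ± 0.38), Gbp7 (1.64 ± 0.35) and Igtp (1.42 ± 0.31). Of 23 xenobiotic metabolism genes, 4 passed (7 adjusted over the list alone; median 0.52; adjusted p = 8.16e-15, and adjusted p = 0.0252 with an estimated correlation). Gsta1 (chromosome 9, 78230669 to 78242683) differed by 5 ± 0.85 (adjusted p = 0.00323), Cbr3 by 4.14 ± 0.56 (adjusted p = 0.000398) and Nqo1 by 2.09 ± 0.32. Gsta1 lay at 17.2 ± 6.03 CPM (SD, n = 5) in old Myc livers, 0.806 ± 0.546 (n = 5) in old mApple livers of the same batch, 0.445 ± 0.513 (n = 4) in young Myc livers and 0.666 ± 0.29 (n = 5) in young mApple livers. Gstm3 differed by 4.22 ± 0.61 and Ly6a, a surface protein gene counted on different transcripts in the 2 tables, by 3.53 ± 0.49. Of 28 mitosis genes, 0 passed in edgeR over all genes or adjusted over the list alone (median 0.64, or 0.4 to 1.11 with 1 library left out). Mitosis as a list had adjusted p = 3.53e-06, and adjusted p = 0.773 with an estimated correlation.

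In all, 49 of 13793 genes passed for the difference of the Myc effect, each of them higher, and 11 of 35 lists did, 4 of them also with an estimated correlation. DESeq2 called 123 higher and 18 lower, and both batches with a batch term gave 26 higher and 11 lower. Without young mApple replicate 4 the count was 74. Myc itself differed by -0.03 ± 0.54 (adjusted p = 0.989).

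**Figure D4:**
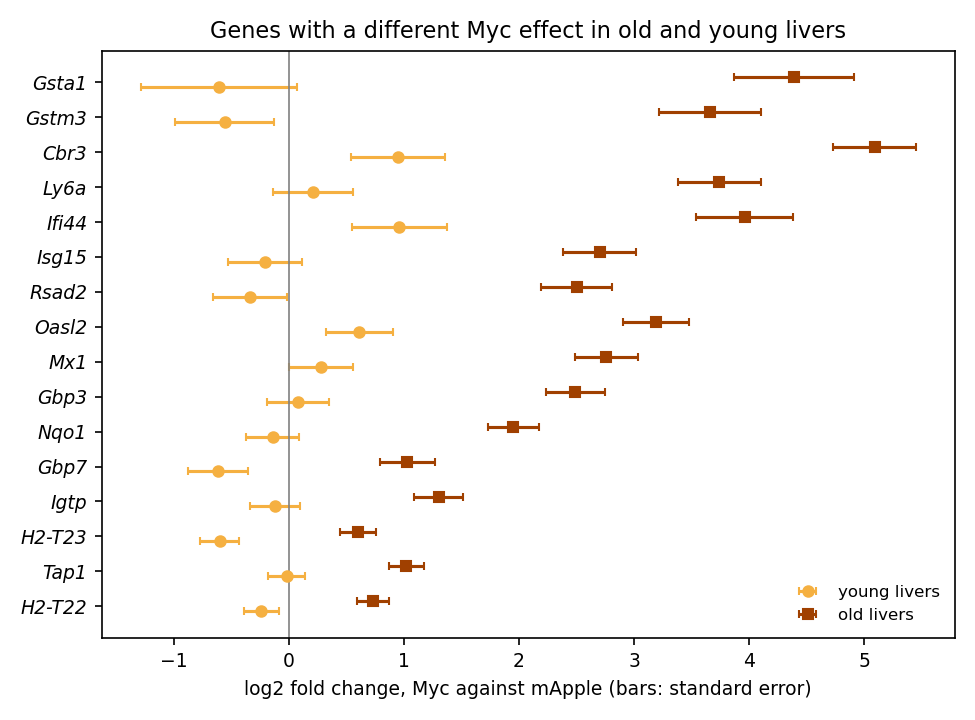
Log2 fold change of Myc against mApple with its standard error for 16 genes that passed the test of the difference, in young (circles, n = 4 against 5) and old (squares, n = 5 against 5) livers. Gsta1 lies at -0.61 in young and 4.39 in old livers, and Mx1 at 0.28 and 2.76.

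Old against young mApple livers showed what age changes without an oncogene. Among the lists, 12 of 14 monocyte, 11 of 13 B cell and 9 of 17 senescence-associated secretory genes rose, and 9 of 16 periportal and 8 of 17 male-biased genes fell. These lists passed with camera and lost the call (adjusted p = 0.251, 0.312, 0.234, 0.234 and 0.327 with an estimated correlation). Old mApple replicate 7 held the highest monocyte, B cell and secretory means of the old mApple libraries (4.84, 2.76 and 3.17 log2 CPM). Without it and old Ccnd1 replicate 5 these lists passed with medians of 1, 0.92 and 1.27 (camera adjusted p = 3.96e-07, 4.52e-05 and 2.83e-06). Of 14 monocyte and infiltrating macrophage markers, 12 rose (13 adjusted over the list alone; median log2 fold change 1.75), among them Cx3cr1 (a chemokine receptor, chromosome 9, 120048683 to 120068296) by 2.14 ± 0.27 (adjusted p = 5.78e-07) and Gpnmb (a glycoprotein of lipid-laden macrophages, chromosome 6, 49036518 to 49058182) by 3.55 ± 0.6. Of 13 B and plasma cell markers, 11 rose (12 adjusted over the list alone; median 1.51), among them Jchain (the joining chain of IgA and IgM, chromosome 5, 88519809 to 88527897) by 3.03 ± 0.5. Of 17 genes on the senescence-associated secretory list, 9 rose (13 adjusted over the list alone, median 1.92), among them Mmp12 by 3.89 ± 0.72. Cdkn2a (the p16 and p19 cell cycle inhibitors, chromosome 4, 89274473 to 89282192), which the list holds although its products are not secreted, rose by 2.84 ± 0.56. The 3 lists passed with camera (adjusted p = 1.69e-07, 4.19e-06 and 4.39e-06) and not with an estimated correlation.

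Of 24 T and NK cell markers, 10 rose with age in mApple livers (13 adjusted over the list alone; median 1.16), among them Ccl5 by 2.16 ± 0.45. Of 12 neutrophil markers, 8 rose (11 adjusted over the list alone; median 2.39), among them Csf3r by 1.64 ± 0.37. Of 24 acute phase genes, 10 rose (18 adjusted over the list alone; median 1.4), among them Cp (ceruloplasmin) by 0.85 ± 0.21. Their list adjusted p-values were 2.37e-05, 1.41e-05 and 1.41e-05, and adjusted p = 0.48, 0.356 and 0.48 with an estimated correlation. Of 13 bile duct markers, 8 rose (11 adjusted over the list alone; median 0.86), among them Krt7 by 1.39 ± 0.34. Of 21 stellate cell and matrix genes, 10 rose (10 adjusted over the list alone; median 0.49), among them Col1a1 by 2.04 ± 0.47. The bile duct and matrix lists had adjusted p = 1.41e-05 and 0.00115, and adjusted p = 0.234 and 0.48 with an estimated correlation. Of 10 fetal and tumour-associated genes, 5 rose (7 adjusted over the list alone; median 0.87), among them H19 by 2.39 ± 0.61. Of 13 immediate early genes, 8 rose (9 higher and 1 lower adjusted over the list alone; median 0.84), among them Fos by 1.76 ± 0.36. The fetal and immediate early lists had adjusted p = 0.000365 and 3.9e-05, and adjusted p = 0.234 with an estimated correlation for each. Without old mApple replicate 7 the medians were 0.58 for T and NK, 1.77 for neutrophil, 0.29 for stellate and matrix and 0.47 for fetal genes, and these lists passed with 4, 2, 4 and 3 members higher.

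Of 16 periportal genes, 9 fell and 1 rose with age in mApple livers (11 and 1 adjusted over the list alone; median -0.58), among them the urea cycle gene Ass1 (-1.03 ± 0.21). Of 17 male-biased genes, 8 fell (9 lower and 1 higher adjusted over the list alone; median -1.13), among them Cyp4a12b (-1.67 ± 0.39). These lists had adjusted p = 1.96e-05 and 1.77e-05, and adjusted p = 0.234 and 0.327 with an estimated correlation. Of 14 bile acid genes, 3 fell (4 adjusted over the list alone; median -0.37; list adjusted p = 0.0217, and adjusted p = 0.48 with an estimated correlation; adjusted p = 0.0655 without old mApple replicate 7). Odc1 (ornithine decarboxylase, an enzyme of polyamine synthesis that the ribosome biogenesis list holds, chromosome 12, 17544873 to 17551502) fell by 0.62 ± 0.13 on the log2 scale. It was 1 of 12 members of that list that fell, of 39 (15 adjusted over the list alone, median -0.17). Ribosome biogenesis as a list had adjusted p = 9.6e-05, and adjusted p = 0.325 with an estimated correlation. Fatty acid oxidation passed as lower with a median of -0.1 and a mean of 0.21 (adjusted p = 0.0437, and adjusted p = 0.729 with an estimated correlation). With each of the 19 libraries left out in turn its median ranged from -0.51 to 0 and its call ended in 13 fits. Among these was the fit without old mApple replicate 7 (adjusted p = 0.22). Thrsp, a gene of lipid synthesis (-2.35 ± 0.48), the hepcidin gene Hamp2 (-2.7 ± 0.58) and the urinary protein gene Mup17, uncertain for its paralogs (-3.17 ± 0.91), fell. The 18 circadian clock genes did not pass as a list (median -0.25, adjusted p = 0.255). In young mApple replicates 3 and 4 of batch 1, Dbp lay at 2.13 and 116.5 CPM and Arntl at 40.7 and 7.76, values chosen after they were seen. Clock genes can thus move oppositely, so the list test cannot show a shift of clock phase. The interferon-stimulated genes had a median of 0.25 and did not pass (adjusted p = 0.0822), with Zbp1 (1.64 ± 0.4) and Oas1a (1.01 ± 0.3) higher and Bst2 (-0.44 ± 0.14) lower.

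In all, 3115 of 14232 genes passed between old and young mApple livers, 1493 higher and 1622 lower, and 21 of 35 lists did, 0 of them with an estimated correlation. Fits of only the groups compared, with no batch term and without the libraries with TMM factors above 1.3 called 1659, 1855 and 2037 genes. Batch 1 alone called 640 genes and batch 2 alone 2333. In the same order the medians were 0.77 and 2.75 for monocyte markers, 1.02 and 2.07 for B cell markers, 0.71 and 3.87 for secretory genes, 0.62 and 6.29 for neutrophil markers, -0.19 and 2.59 for acute phase genes and -0.21 and 0.88 for the interferon-stimulated genes. Without old mApple replicate 7, whose Kupffer marker mean of 7.82 log2 CPM compares with 3.63, 5.08 and 4.64 in the other old mApple libraries of batch 2, the count was 1810. Libraries scaled to their total counts moved the median of all genes by 0.1 and gave 2003 higher and 885 lower genes. The interferon-stimulated list passed without young mApple replicates 1 (0.29) or 2 (0.28) or old mApple replicates 1 (0.28), 2 (0.3), 3 (0.29), 5 (0.28) or 6 (0.31).

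Old against young Ccnd1 livers showed higher B cell, T cell and MHC class II genes with age, in lists that passed with camera and lost the call (adjusted p = 0.183 with an estimated correlation for each). Old Ccnd1 replicate 5 held T and NK cell, MHC class II and B cell means of 2.59, 4.61 and 2.07 log2 CPM, against -0.28 to 1.39, 1.89 to 3.42 and 1.02 to 1.73 in the other old Ccnd1 libraries of batch 2. Without it and old mApple replicate 7 the medians were 1.43, 1.25 and 1.78, and the lists passed with camera. Of 13 B and plasma cell markers, 10 rose (12 adjusted over the list alone; median log2 fold change 1.71), among them Jchain by 3.49 ± 0.56 (adjusted p = 0.000115) and Ms4a1 (CD20) by 2.31 ± 0.4. Of 24 T and NK cell markers, 14 rose (19 adjusted over the list alone; median 1.71), among them Cd8a by 2.84 ± 0.57. Of 14 MHC class II and dendritic cell markers, 11 rose (13 adjusted over the list alone; median 1.54), among them Itgax by 1.98 ± 0.42 and H2-Aa by 1.87 ± 0.43. Of 17 genes on the senescence-associated secretory list, 4 rose (9 adjusted over the list alone, median 1.4, and 0.78 without old Ccnd1 replicate 5), among them Cdkn2a, whose products are not secreted, by 3.11 ± 0.61. Of 11 female-biased liver genes, 5 rose (6 adjusted over the list alone, median 1.68, or 1.24 to 2.71 with 1 library left out), among them Cyp2b9 by 4.53 ± 1.01. These 5 lists passed with camera (adjusted p = 3.28e-12, 7.57e-11, 6.12e-09, 5.54e-06 and 0.00406), and adjusted p = 0.183 with an estimated correlation for each.

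Of 17 male-biased genes, 5 fell with age in Ccnd1 livers (10 adjusted over the list alone; median -0.88), among them Elovl3 (-2.79 ± 0.62). The male-biased genes as a list had adjusted p = 1.05e-08, and adjusted p = 0.183 with an estimated correlation. Of 18 stress response genes of the integrated stress and unfolded protein response, 1 rose and 1 fell (1 and 5 adjusted over the list alone; median -0.43). Stress responses as a list had adjusted p = 0.0125, and adjusted p = 0.459 with an estimated correlation. Of 42 interferon-stimulated genes, 1 rose, Mx1 by 0.99 ± 0.33 (adjusted p = 0.0465), with 0 adjusted over the list alone and a median of 0.28 (list adjusted p = 0.00406, and adjusted p = 0.723 with an estimated correlation). In all, 1589 of 14232 genes passed, 862 higher and 727 lower, and 20 of 35 lists did, 0 of them with an estimated correlation. Batch 1 alone called 203 genes and batch 2 alone 56, and the count was 871 without old Ccnd1 replicate 5 and 1029 without young Ccnd1 replicate 6. Libraries scaled to their total counts moved the median of all genes by 0.14 and gave 1025 higher and 193 lower genes.

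Old against young Myc livers showed higher interferon, antigen presentation and B cell genes with age. Of 42 interferon-stimulated genes, 28 rose (38 adjusted over the list alone; median log2 fold change 1.13), among them Oasl2 by 2.71 ± 0.3 (adjusted p = 5.11e-06), Xaf1 by 1.65 ± 0.24 and Irf7 by 1.59 ± 0.24. Of 18 MHC class I presentation genes, 12 rose (16 adjusted over the list alone; median 0.71), among them H2-Q4, uncertain for its paralogs, by 1.15 ± 0.17. Of 20 interferon-gamma-inducible genes, 9 rose (15 adjusted over the list alone; median 1.05). Of 13 B and plasma cell markers, 8 rose (12 adjusted over the list alone; median 1.59), among them Cd79a by 2.56 ± 0.4. Of 16 senescence-associated secretory genes, Mmp13 rose by 1.76 ± 0.44 as the 1 member past the test (5 adjusted over the list alone; median 0.8). These 5 lists passed with camera (adjusted p = 3.28e-54, 2.55e-21, 4.65e-19, 5.37e-16 and 0.000165) and with an estimated correlation (adjusted p = 0.00573, 0.00573, 0.0147, 0.00735 and 0.0147).

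Cbr3 (4.42 ± 0.38), Gsta1 (5.3 ± 0.61) and Nqo1 (2.1 ± 0.24) were higher in old than in young Myc livers, 3 of 8 xenobiotic metabolism genes that rose of 23 (8 adjusted over the list alone; median 0.22, and 0.09 without young Myc replicate 1). The list had adjusted p = 2.18e-09, and adjusted p = 0.0724 with an estimated correlation. Of T and NK cell, MHC class II and monocyte markers 4, 1 and 2 rose (medians 1, 0.81 and 0.13; list adjusted p = 6.01e-06, 4.47e-05 and 0.00103, and adjusted p = 0.257, 0.257 and 0.333 with an estimated correlation). Without old Myc replicate 5 the T and NK median was 0.46 with 1 member higher, and without young Myc replicate 1 the monocyte median was 1.36 with 4 higher, both lists past the threshold. Cidec, a lipid droplet protein gene, rose by 3.52 ± 0.76, and Odc1 (-0.73 ± 0.15) and Herpud1 (-0.94 ± 0.2) fell. The 8 red blood cell genes had a median of -0.96, with 5 lower adjusted over the list alone and 0 in edgeR over all genes (list adjusted p = 0.00353, and adjusted p = 0.329 with an estimated correlation). This rested on young Myc replicate 1 (mean 7.05 log2 CPM, other Myc libraries 4.81 to 5.2), without which the median was -0.04 and the list did not pass (adjusted p = 0.815). In all, 411 of 13793 genes passed (n = 5 against 4), 317 higher and 94 lower, and 26 of 35 lists did, 5 of them also with an estimated correlation. The count was 270 without young Myc replicate 3, and libraries scaled to their total counts moved the median of all genes by 0.15 and gave 583 higher and 49 lower genes. Without the libraries that held over 1 CPM of Cpa1 the count was 173, and with both batches and a batch term it was 219.

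The Ccnd1 effects of the batches, fitted apart, were compared across 12891 genes, which are not independent replicates, and the libraries compared share no control. In young livers the log2 fold changes correlated with Pearson's r = 0.395 and Spearman's rho = 0.282, and 82.3% of the 271 genes called in either batch had the same sign in both. In old livers r was 0.044 and rho 0.011, and 54.5% of 407 called genes had the same sign. The Ccnd1 effect of batch 2 and the Myc effect of batch 1 correlated with r = 0.417 (rho 0.296) in young and r = 0.236 (rho 0.13) in old livers. The age difference of mApple livers correlated between the batches with r = 0.357 and rho = 0.328, and 74% of 2745 called genes had the same sign.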

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

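The tests of the Myc level, of leukocytes, of pancreatic tissue and of the libraries that stand apart were chosen after the results had been seen, while the tests with a library left out (for lists other than the interferon-stimulated genes excepted), with other splits, for outlying libraries and for differences between the ages were not.

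The interferon-stimulated genes rose more under Myc in old than in young livers, by a median log2 value of 1.4 over 42 genes (SE of the mean 0.13), with 41 of them positive. A lower level of Myc RNA in the young Myc livers was not seen, since old and young Myc livers differed in Myc by -0.08 ± 0.38. The upper end of 0.67 (estimate plus 2 SE) lies under that median. How steeply these genes follow Myc is not known, so a Myc difference within that range is not excluded as a cause. More leukocytes in the old Myc livers, as the whole cause, were argued against by their own markers, whose highest median difference was 0.55 (T and NK cells, SE of the mean 0.2), with B cells at 0.49 (-0.09 and 0.2 without old Myc replicate 5), Kupffer cells at 0, monocytes at -0.46 and neutrophils at -2.91, the last 2 resting on young Myc replicate 1, without which they stood at 0.56 and 0.1. In all 19 fits with 1 library left out the interferon list passed, with a lowest median of 1.26. Each leukocyte median, at most 0.84, then lay more than 2 SE below the interferon median. List SEs are over genes, which vary together, and do not measure the spread between livers. An age-dependent response of the liver to Myc may underlie the difference, as a hypothesis found and tested on the same libraries. Age cannot be told apart from birth cohort here, and Myc protein, interferon protein and the vector dose were not measured.

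Other gene lists differed in the Myc effect between old and young livers, as did 49 genes. The interferon-gamma-inducible genes (1.05), MHC class I presentation (0.72) and xenobiotic metabolism (0.52) passed also with an estimated correlation. DNA replication (median 0.31), mitosis (0.64), MHC class II and dendritic cell markers (0.47) and stellate cell and matrix genes (0.23) were higher and lost the call (adjusted p = 0.476, 0.773, 0.81 and 0.773 with an estimated correlation). Male-biased genes (-0.67), acute phase genes (-0.81) and neutrophil markers (-2.91) were lower and lost it too (adjusted p = 0.773, 0.81 and 0.773 with an estimated correlation). Young Myc replicate 1 held the highest acute phase and neutrophil means of the 4 young Myc libraries, at 10.92 and 4.07 log2 CPM, and without it the neutrophil and acute phase differences were 0.1 and 0.29 and neither list passed (adjusted p = 0.741 and 0.988). With each of the 19 libraries left out in turn, the calls of stellate cell and matrix genes, MHC class II markers, acute phase genes and male-biased genes ended in 10, 8, 4 and 2 fits. Among enzymes the differences were 5 for Gsta1, 4.22 for Gstm3, 4.14 for Cbr3 and 2.09 for Nqo1, and among interferon-stimulated genes 3 for Ifi44, 2.91 for Isg15, 2.84 for Rsad2, 2.58 for Oasl2 and 2.48 for Mx1. Ly6a differed by 3.53, Gbp3 by 2.41, Gbp7 by 1.64, Igtp by 1.42, H2-T23 by 1.19, Tap1 by 1.04 and H2-T22 by 0.97.

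For the Ccnd1 effect, 10 lists differed between old and young livers with camera. MHC class II and dendritic cell markers (median 0.57), lipogenesis (0.51), periportal genes (0.18), xenobiotic metabolism (0.18) and stellate cell and matrix genes (0.11) were higher. Their calls were lost (adjusted p = 0.94, 0.524, 0.94, 0.94 and 0.967 with an estimated correlation). Acute phase genes (-2.11), neutrophil markers (-2.25), mitosis (-0.62), cholesterol synthesis (-0.32) and stress responses (-0.23) were lower, with adjusted p = 0.524, 0.94, 0.967, 0.967 and 0.94 with an estimated correlation. For mitosis the direction depends on the batch, with medians of 0.53 in batch 1 alone and -1.62 in batch 2 alone, each past the threshold, and the test turned at -0.06 without the libraries with TMM factors above 1.3. The acute phase and neutrophil lists did not pass in batch 1 alone (-0.37 and -0.56, adjusted p = 0.0701 and 0.146). With each of the 35 libraries left out in turn, the calls of stress responses, mitosis, stellate cell and matrix genes, cholesterol synthesis and periportal genes ended in 14, 13, 6, 4 and 1 fits. The medians then ranged over 0.27 to 1.11 for MHC class II, 0.12 to 0.36 for periportal and 0.07 to 0.32 for xenobiotic metabolism genes. They ranged over 0 to 0.59 for stellate cell and matrix genes and -3.86 to -1.4 for neutrophil markers.

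Pancreatic enzyme genes stood out in 4 libraries of batch 1 with over 1 CPM of Cpa1, namely young Myc replicates 2 and 4, old Myc replicate 3 and young Ccnd1 replicate 4. The log2 levels of 15 acinar genes correlated between these libraries with a lowest pairwise r of 0.87 over 6 pairs, across genes, which are not independent replicates. A piece of pancreas in these samples is a candidate source, with that value in the range it needs. An effect of Myc on these genes was argued against, since 5 of the 9 Myc libraries lay at or below the highest mApple library of batch 1 and 1 of 8 Ccnd1 libraries lay above it. No other biological explanation was tested.

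Old mApple replicate 7 and old Ccnd1 replicate 5, both of batch 2, had TMM factors above 1.3 and differed from the other old libraries of that batch. Fewer hepatocytes in the piece sampled, as the whole cause, were argued against, since the other cell types moved apart: endothelial markers stood at a median of 0.04, bile duct markers at -0.37 and stellate cell and matrix genes at 1.02 (SE 0.18), while Kupffer markers stood 2.55 ± 0.34 (SE) above the endothelial ones. The SEs in this paragraph are also over genes that vary together, not between livers. Depth was argued against, since 2 of 2 total counts lay within the range of the other batch 2 libraries, and 1 scaling factor per library cannot part these lists. Leukocytes in the piece sampled may account for part of the pattern, since 5 of 5 leukocyte lists were raised by more than 2 SE in both (medians 2.59 for Kupffer cells, 2.34 for monocytes, 2.32 for T and NK cells, 2.1 for B cells and 2.54 for neutrophils). Mitosis genes stood 1.99 higher and hepatocyte identity genes at -0.88, and whether the leukocytes come from the liver, from disease of the old mice or from the sampling was not tested.

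Of 72 sets of values (9 measures in 8 groups of at least 4 libraries in a batch), 12 held an outlying library, where chance flags about 1 in 20. In batch 1, acinar genes were outlying in old Myc replicate 3 (3.05 log2 CPM, others -4.32 to -3.05) and young Ccnd1 replicate 4 (2.43), and in batch 2 in young mApple replicate 10 (-0.747, others -3.3 to -3.03). Acute phase means were outlying in young mApple replicate 2 (10.5, others 6.76 to 6.93) and old mApple replicate 4 (8.94), whose mitosis mean was outlying as well (0.961, others -0.958 to -0.489). Monocyte markers were outlying in old mApple replicate 7 (4.84, others 2.07 to 2.25) and young Myc replicate 1 (3.49, others 0.996 to 1.39), and B cell markers in young Ccnd1 replicate 5 (-0.999). Ccnd1 lay at 96.1 CPM in old Myc replicate 5 (others 19.9 to 39.9) and Myc at 27.4 CPM in young mApple replicate 8 (others 3.06 to 8.51). Old mApple replicate 9 had a total of 9796128 counts against 8391923 to 8620147 in the other 3.

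The 2 libraries in no group held Ccnd1 at 313.8 and 909.6 CPM, above the 12.6 to 116.8 CPM of the 9 mApple libraries of batch 2.

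Other splits of the libraries into groups of the same sizes within each batch, 100 per comparison with the real one, tested whether chance could give as many calls. Where 1 of 100, the real split, called as many genes, chance is unlikely but not excluded, as 100 splits can show no smaller share. That holds for Ccnd1 in young livers (418, highest other 1), Myc in young livers (1829, highest other 1128) and Myc in old livers (2367, highest other 186). It holds as well for age in mApple (3115, highest other 940), Ccnd1 (1589, highest other 1) and Myc livers (411, highest other 129), and for the difference of the Myc effect (49, highest other 41). For that difference the age labels were redrawn within each transgene. Such redrawing turns the age effect shared by mApple and Myc livers into spread, so it does not isolate the difference, and 49 lies near 41. For Ccnd1 in old livers chance is not made unlikely, since 6 of the 100 splits called at least the real 125 genes. The highest other split called 2639, and what it separates was not tested. For the difference of the Ccnd1 effect the real split called 0 genes in edgeR (1280 at an unadjusted p under 0.05, 22 in DESeq2), so 100 of 100 splits called as many, with 31 in the highest other.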

How the results depend on the processing

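The settings without libraries with a TMM factor above 1.3 or with over 1 CPM of Cpa1, the doubling of the batch 2 values, and leaving out 1 library for lists other than the interferon-stimulated genes or for 4 leukocyte genes were chosen after the data had been seen. No paired analysis was possible because the library numbers in the labels differ between the groups, and numbers within a group were given in order only to name libraries. Over all settings, 209 of 256 counts of genes lay within 1.5 times the reported one, the interferon-stimulated list kept its direction and its side of the threshold in 176 of 192 values, and the named genes did so in 1126 of 1329 values. Of the other named genes' values, 186 kept the direction and no longer passed. For 5 values DESeq2 gave no adjusted p. Where a value below moved, turned or crossed the threshold, the cause was not tested, except that the settings with a batch, with fewer groups or with libraries left out rest on fewer libraries. Depth limits genes at a few counts, and batch 2, with fewer counts in genes, gives the lower counting precision per library.

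DESeq2 called 229 genes for Ccnd1 in old livers, 22 for the difference of the Ccnd1 effect and 141 for that of Myc. With no batch term the counts were 192 (Ccnd1, young), 62 (Ccnd1, old) and 1855 (age, mApple). Batch 1 alone called 265 (Ccnd1, young), 640 (age, mApple) and 203 (age, Ccnd1), and batch 2 alone 11 (Ccnd1, young), 242 (Ccnd1, old), 56 (age, Ccnd1) and 28 (difference of the Ccnd1 effect). Fits of only the groups compared called 12 (Ccnd1, old), 497 (Myc, young) and 1659 (age, mApple). With at least a 2-fold change asked for, 178 and 82 genes passed for Ccnd1 in young and old livers, 509 and 727 for Myc, and 812, 611 and 249 for age in mApple, Ccnd1 and Myc livers. For age in Myc livers, total library sizes gave 632 and both batches with a batch term 219. Without the libraries with high TMM factors the counts were 638 (Ccnd1, young), 497 (Ccnd1, old), 2037 (age, mApple) and 2 (difference of the Ccnd1 effect), and without those with Cpa1 173 (age, Myc).

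With an estimated correlation 2, 4, 2 and 6 lists passed for Ccnd1 and Myc in young and old livers (Ccnd1 first), 0, 0 and 5 for age in mApple, Ccnd1 and Myc livers, and 0 and 4 for the differences of the Ccnd1 and Myc effects. The interferon-stimulated list (median 0.28) then lost its call for age in Ccnd1 livers. Batch 1 alone gave 12 lists for age in mApple livers and 16 for the difference of the Ccnd1 effect, and 20 passed for Myc in young livers without the Cpa1 libraries, where the interferon median was -0.15. For age in mApple livers the interferon median was -0.21 in batch 1 and 0.88, past the threshold, in batch 2. For the difference of the Ccnd1 effect it was 0.36, past the threshold, in batch 1, -0.31 in batch 2, and 0.09, past the threshold, without the libraries with high TMM factors.

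Lists that turned in batch 1 were, for age in mApple livers, interferon-gamma-inducible genes (-0.07), MHC class I presentation (-0.08), lipogenesis (-0.06) and the acute phase (-0.19), for Ccnd1 in old livers the acute phase (0.02), and for the difference of the Ccnd1 effect mitosis (0.53). The mitosis test also turned without the libraries with high TMM factors (-0.06). Ribosome biogenesis turned for Ccnd1 in young livers in batch 2 (0.02), and the fetal genes for age in Myc livers without the Cpa1 libraries (-0.15). The correlation of Ccnd1 effects between batches in young livers was 0.282 by Spearman and 0.749 over called genes. That of the Ccnd1 and Myc effects was 0.296 and 0.59 in young and 0.13 and 0.338 in old livers.

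With 1 library left out, the counts ranged over 281 to 552 (Ccnd1, young), 65 to 1237 (Ccnd1, old), 1067 to 2235 (Myc, young), 1837 to 2320 (Myc, old), 1810 to 3399 (age, mApple), 871 to 1948 (age, Ccnd1), 270 to 562 (age, Myc), 0 to 4 (difference of the Ccnd1 effect) and 37 to 74 (that of Myc). The interferon medians ranged, in the same order, over 0.76 to 0.92, 0.77 to 1.21, -0.03 to 0.14, 1.34 to 1.55, 0.04 to 0.31, 0.2 to 0.36, 1.05 to 1.28, -0.09 to 0.17 and 1.26 to 1.51. Of the other lists past the threshold, mitosis turned for the difference of the Ccnd1 effect (range -0.81 to 0.08) and the acute phase for that of Myc (-1.87 to 0.29).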

Other observations

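The genes and values here were chosen after they had been seen.

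Of 28 genes known as targets of Nfe2l2 (Nrf2), a transcription factor of the oxidative stress response, many of them of glutathione and NADPH metabolism and others of ferritin, haem breakdown or transport, 11 passed in edgeR for the difference of the Myc effect between old and young livers, each of them higher. The other 17 did not pass (15 positive, median 0.43), among them Gclc (0.43), Gclm (-0.17), Hmox1 (0.14), G6pdx (0.06), Txnrd1 (0.46) and Osgin1 (-0.4). The list was made after the values had been seen and was not tested for enrichment. Sulfiredoxin (Srxn1) differed by 2.1 ± 0.21 (SE, adjusted p = 1.71e-06), glutathione reductase (Gsr) by 0.86 ± 0.13, the carbonyl reductase gene Cbr1 by 1.39 ± 0.23, Gstm1 by 2.03 ± 0.43, Gstm4 by 1.76 ± 0.29, Pgd of the pentose phosphate pathway by 1.15 ± 0.26 and Aldh1a7 by 0.97 ± 0.18. Gsta1, Gstm1, Gstm3 and Gstm4 have close paralogs and are uncertain. Myc raised 19 of the 28 in old livers and 0 in young livers in edgeR, where 5 fell: Srxn1 (-0.49, adjusted p = 0.0303), Gsr (-0.45, adjusted p = 0.00206), Gstm4 (-0.64, adjusted p = 0.0415), Aldh1a7 (-0.45, adjusted p = 0.0252) and Me1 (-1.92, adjusted p = 0.0251).

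Under Ccnd1, Gsta1 lay at 117.9 ± 28.8 CPM (SD, n = 3) in young and 81 ± 25.2 (n = 5) in old livers of batch 2, and at 1.75 ± 0.792 (n = 5) and 2.33 ± 1.44 (n = 3) in batch 1. Gstm3 lay at 593.2 ± 113.2 and 450.3 ± 106.8 CPM in batch 2 and at 53.9 ± 25.9 and 94.6 ± 39.4 in batch 1, with the same n. The mApple libraries of batch 2 lay at 9.38 ± 5.84 (n = 5, young) and 4.46 ± 5.67 (n = 4, old) CPM of Gsta1.

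Transcripts of the interferons themselves were near the floor. Of 18 type I and III interferon genes, 4 had any count, 13 counts in all in 8 of the 44 grouped libraries, with a highest value of 0.16 CPM. Ifng had counts in 23 of the grouped libraries, up to 0.527 CPM, and a floor of 3 counts is up to 0.439 CPM.

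Saa1, an acute phase gene, varied widely within groups. Its 8 highest libraries, in CPM, were young Myc replicate 1 (11085.5), old mApple replicates 6 (9471.3), 8 (5065.3) and 9 (1075.2), young mApple replicate 2 (9042), young Ccnd1 replicates 2 (8455) and 5 (8372.2) and the first library in no group (2110.7).

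The 2 libraries whose title and age disagree are titled young Ccnd1 and carry the birth date of the old mice of batch 2. They held, in order, Myc at 2.54 and 2.08 CPM, Jchain at 3.52 and 1.47 CPM and Cdkn2a at 0.0978 and 0 CPM. Mean log2 CPM was 4.28 and 4.05 for the interferon-stimulated genes, 1.48 and 2.36 for mitosis, 9.22 and 6.88 for the acute phase, -0.99 and -0.77 for B cell markers and 1.47 and 0.75 for monocyte markers. In the batch 2 Ccnd1 groups, B cell means were -0.61 to 0.05 in young and 1.02 to 2.07 in old livers. Monocyte means were 0.55 to 0.75 and 1.75 to 4.41, so both libraries lay below the old ranges of these lists. For mitosis and the acute phase the ranges of the ages overlapped, and which label is right was not tested.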
